A study of Gallus gallus with 6 samples.

How the data were processed

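Total RNA of chicken monoblasts carrying wild type v-Myb (3 biological replicates) or deltaP v-Myb (3 biological replicates) was extracted with Trizol, labelled with biotin and hybridized to Affymetrix chicken arrays, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The deposited table gives 1 log2 expression value per probe set and array, for 38535 probe sets and 6 arrays, with 0 missing values. Partek 6.4 and GCRMA are named in the submitters' processing notes. GCRMA estimates the background from probe sequence, normalizes the arrays to one another by quantiles and summarises the probes of a set. It pulls dim probe sets towards a common floor, so fold changes of dim genes can be compressed or inflated, and the summary values carry no count or depth. The number of arrays limits the precision.

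The table was first checked for pairing of the same-numbered samples. The sums of the same-numbered wild type and deltaP values differed between the 3 replicate numbers by at most 0.00013 log2 units over all 38535 probe sets, all under the tolerance of 0.001. The deviations of same-numbered arrays from their group means were correlated at -1 in each of the 3 pairs. The replicate number had thus been removed from the values as an additive effect before deposit, a step that is not given in the sources used here. The labels do not say what the same-numbered cultures share. The 6 values of a probe set then hold 3 independent differences, and the SD within each group is a fixed share of the SD of these differences. The spread between pairs that was removed cannot be recovered, so a p-value measures the spread of the within-pair differences only.

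The design fixed before the data were examined was limma without a block. That fit counts 4 residual degrees of freedom where the values hold 2. On simulated values with no change and the same centring, over 16199 probe sets, 19.3% of p-values lay under 0.05 without the block and 5% with it. The mean number of calls was 200.2 (at most 279) without the block and 0.1 (at most 1) with it, over 10 simulated tables. With 200 changed probe sets, the fit with the block found 16% of those changed 2-fold and 95.2% of those changed 8-fold with 7.3 false calls on average, and the fit without it found 77.8% and 98.8% with 438 false calls. The fit with the replicate number as a block is therefore reported as the main result, a change made after the structure of the values was seen, and the counts of calls in the fit fixed first are printed beside it, with its adjusted p for CDKN2A and for the 10 genes with the smallest p.

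Probe sets were kept when their log2 value was over 4 in at least 3 of the 6 arrays, which left 16199 (42.1%) of the 38439 that are not controls. Differences were tested with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), two-sided, with the Benjamini-Hochberg threshold at 0.05. Gene symbols came from the platform annotation (dated 2016), in which 27168 probe sets had 1 gene symbol, 177 several and 11094 none. Symbols were checked through the gene identifier against a RefSeq gene table of assembly GRCg7b. It matched 26853 of the probe sets with 1 symbol, changed 0 symbols and left 315 as annotated. That table was also used for the chromosome of each gene and for the neighbours of CDKN2A; no coordinates are given because no build is named for the array annotation. A gene was represented by its brightest probe set over all 6 arrays, which gave 7768 tested genes, 3612 of them with several tested probe sets. Genes were counted by their Entrez identifier. The symbol CIITA stands for 2 identifiers in the annotation, and both entered the interferon list. Probe sets with several symbols named no gene.

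The 24 gene lists, the filter, the thresholds and the alternatives were chosen before the data were examined. List entries were matched by symbol (827 entries) or, failing that, by a synonym in the gene table (24 entries), and 190 entries matched no annotated gene; every gene that matched an entry was used, and genes are named by the symbol of the table. Lists with at least 5 tested members (23 of 24) were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives, and of the calls with the preset correlation 0 held in either. Members were also adjusted over the list alone. A list-alone p in the text is the limma p of the gene after Benjamini-Hochberg adjustment within that list.

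The genes named in the text followed a rule: CDKN2A, CDKN2B, MYB and LECT2 in any case, the genes with the largest change among those past the threshold or, with fewer than 5 in a direction, the 5 with the smallest p in that direction, and in each list up to 4 members with the smallest p or those needed to say what moved. Since no gene passed over all genes, the second part gave the 5 with the smallest p in each direction. Genes named outside this rule are said to be so. For CDKN2A, CDKN2B, LECT2 and MYB exact two-sided permutation tests of 3 against 3 arrays and of the 3 pair signs were also run. The smallest p these allow are 0.1 and 0.25. On values centred within pairs the 6 arrays are not exchangeable, so the first of these tests adds nothing to the pair signs.

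The alternatives were no filter, a filter at a log2 value of 6, another quantile normalization, centring of each array on its median, no intensity trend, robust moderation, a threshold of 2-fold, the mean of a gene's probe sets, and leaving out each array. With the block, leaving out 1 array also removes the information in its partner. Weights for each pair and leaving out the genes of chromosomes Z and W were chosen after seeing the data. Where the interferon list was compared with chance, 10000 random lists matched on expression level were drawn.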

Results

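Gene expression was measured in chicken monoblasts, the immature precursors of monocytes and macrophages, from Brown Leghorn birds. The cells had been transformed either by wild type v-Myb, the transcription factor oncoprotein of avian myeloblastosis virus, or by a mutated v-Myb designated deltaP. Total RNA from 3 biological replicates of each group was labelled with biotin and hybridized to 6 Affymetrix chicken arrays, 1 per replicate. The series title concerns the dependence of INK4A expression on the leucine zipper region of v-Myb. The labels do not say which residues deltaP alters, so the groups are called wild type and deltaP here. The value table held 38535 probe sets on the log2 scale, of which 96 were array controls. The share of the other probe sets above a log2 value of 4 was between 41.8% and 42% on every array. The number of arrays limits the precision of each value.

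For every probe set the mean of the same-numbered wild type and deltaP arrays was equal over the 3 replicate numbers, to within 0.001 log2 units. The deposited values therefore carry 3 independent differences, 1 within each same-numbered pair, and errors are given below as the SD of these differences. The deposited value of a single array is not its measured level.

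The first question was how the INK4 locus differed between the groups. CDKN2A, which in mammals encodes the cell cycle inhibitor INK4A and the p53 regulator ARF, was 6.79-fold higher in deltaP cells. Its probe set (Entrez gene 395077) had a mean log2 value of 8.47 in wild type cells and 11.24 in deltaP cells. The log2 difference was 2.76 ± 0.98 (SD, n = 3 pairs), with values of 3.88, 2.04 and 2.37 in pairs 1, 2 and 3. The deltaP arrays had values of 11.8, 10.88 and 11.04 and the wild type arrays 7.92, 8.84 and 8.67. CDKN2B, which encodes the neighbouring inhibitor INK4B, was dim in both groups, with mean log2 values of 2.07 and 3.08. Its difference came from pair 1 (2.96), against 0.03 in pair 2 and 0.05 in pair 3.

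In limma with the replicate number as a block, CDKN2A had an unadjusted p of 0.000269 and an adjusted p of 0.166 over all 7768 genes tested, and it was higher in 3 of 3 pairs. Adjusted over the list alone (20 tested INK4/CIP, p53 and RB genes, which included CDKN2A because the series title names INK4A), limma gave an adjusted p of 0.00537. That list is therefore not independent evidence for the gene. Over the alternatives the list-alone p lay between 0.000436 and 0.0468. Without the block, limma gave an adjusted p of 0.0118 over all genes, and with the block and pair weights, chosen after seeing the data, 0.0464. The 95% confidence interval of the log2 difference ran from 1.86 to 3.66 in the probe set fit with the block, where the adjusted p was 0.228. The exact two-sided test of the 3 pair signs gave 0.25, the smallest p that 3 pairs allow. The exact permutation test of 3 against 3 arrays, fixed in advance, gave its smallest p of 0.1, but on values centred within pairs that result follows from the pair signs and is no separate evidence. The annotation used here does not say which transcript or product of chicken CDKN2A the probe set stands for, so the value cannot be read as INK4A itself.

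**Figure D1:**
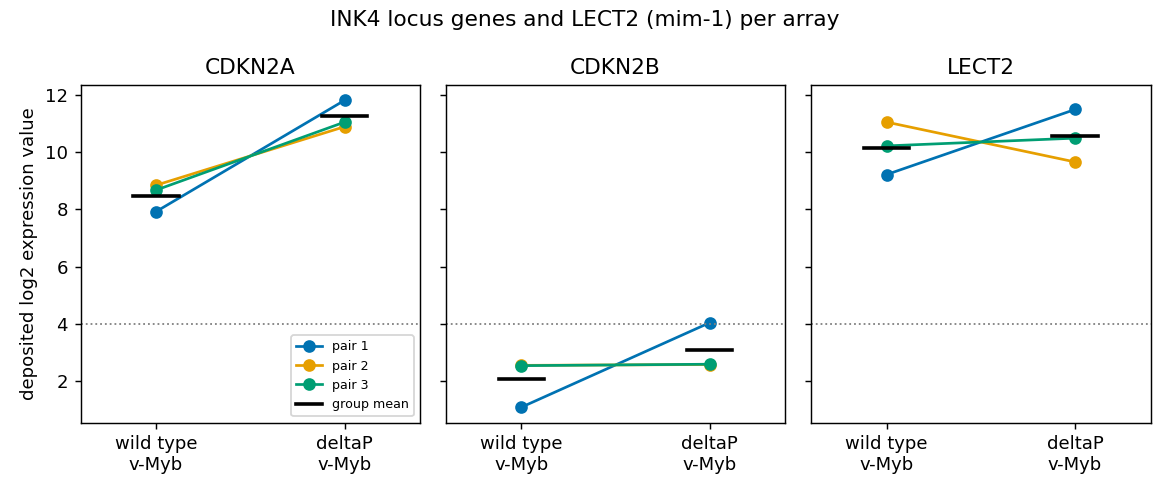
Deposited log2 expression values of CDKN2A, CDKN2B and LECT2 on each of the 6 arrays, with a line joining the wild type and deltaP arrays of each same-numbered pair, a black bar at each group mean and a dotted line at the filter value of 4. CDKN2A was higher in deltaP in every pair, CDKN2B lay at or below about 4 on every array, and the LECT2 differences had both signs.

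No other regulator of the same axis passed the list-alone threshold. Of the 20 tested members, 8 were higher and 12 lower in deltaP, with a median log2 difference of -0.08. E2F4, an E2F transcription factor, was 1.32-fold higher (list-alone adjusted p = 0.179 in limma). CCND1, which encodes cyclin D1, was 1.64-fold lower with pair differences of -1.48, -0.75 and 0.08 (list-alone adjusted p = 0.366), and GADD45A was 1.49-fold lower (list-alone adjusted p = 0.366). Camera gave an adjusted p of 0.987 for this list. Among 14 tested Polycomb and other repressors of the locus, 5 were higher and 9 lower. EED, a core subunit of Polycomb repressive complex 2, was 1.3-fold lower, HDAC1 was 1.25-fold lower and EZH2 was 1.19-fold higher, with list-alone p of 0.274, 0.316 and 0.327 in limma. The camera adjusted p of that list was 0.657.

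The other genes fixed in advance were the Myb gene itself and a classic Myb target. LECT2, known in chicken as mim-1, had mean log2 values of 10.15 in wild type and 10.54 in deltaP cells. Its pair differences were 2.28, -1.39 and 0.27, and limma gave an adjusted p of 0.87, so the difference was smaller than the spread between pairs. The MYB probe set (Entrez gene 396244) stayed at background in both groups (2.15 and 2.17), so it gave no check of the v-Myb transgenes.

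Over the whole array, the genes with the smallest p had varied known functions, and none passed the threshold. SERPINB10B, the chromatin-associated serpin MENT of avian granulocytes, was 4.87-fold higher in deltaP, with a log2 difference of 2.28 ± 0.3 (SD, n = 3 pairs). The calcium-binding protein gene S100A12, for which the gene table lists S100A9 as a synonym, was 4.51-fold higher (2.17 ± 0.52). LGALS1A, a galectin, was 2.07-fold higher (1.05 ± 0.13). KCNMB1, a regulatory subunit of calcium-activated potassium channels, was 6.55-fold higher (2.71 ± 0.81). CDK14, a cyclin-dependent kinase, was 6.01-fold higher (2.59 ± 0.69) from a mean log2 value of 2.84 in wild type cells, below the filter value.

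In the other direction, TARP, a T cell receptor gamma chain reading frame, was 8.35-fold lower in deltaP. Its mean log2 value was 10.75 in wild type and 7.69 in deltaP cells, and all 3 of its tested probe sets were lower. UGT8, a galactosyltransferase of sphingolipid synthesis, was 2.84-fold lower, and FGGY, a carbohydrate kinase, was 2.76-fold lower. The SDs of their 3 pair differences were 0.2 and 0.15 log2 units. SYNE2, a protein of the nuclear envelope, was 3.66-fold lower by its brightest probe set. A second SYNE2 probe set had differences of -2.17, -3.02 and 0.32 in pairs 1, 2 and 3, so it was not lower in pair 3. CDH23, a cadherin, was 4.7-fold lower and reached a mean log2 value of 3.35 in deltaP, below the filter value.

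These 10 genes were the 5 with the smallest p in each direction, and their adjusted p in limma with the block ran from 0.11 to 0.166. Without the block all 10 passed, with adjusted p from 0.00387 to 0.0101. With the block, limma called 0 of 16199 probe sets and 0 of 7768 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 771 genes, 302 higher and 469 lower in deltaP, where chance alone would give 388, and 1500 probe sets (583 higher and 917 lower), where chance would give 810. The limma fit without the block called 640 genes (276 higher, 364 lower) and 1120 probe sets (453 higher, 667 lower). Of those 640 genes, 515 had an unadjusted p under 0.05 with the block. Across all tested genes, 2589 (33.3%) had the same direction in all 3 pairs, against 25% by chance. Simulated data with no change and the same pair structure gave 200.2 probe set calls on average without the block and 0.1 with it, so the count without the block is not a count at its stated error rate.

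**Figure D2:**
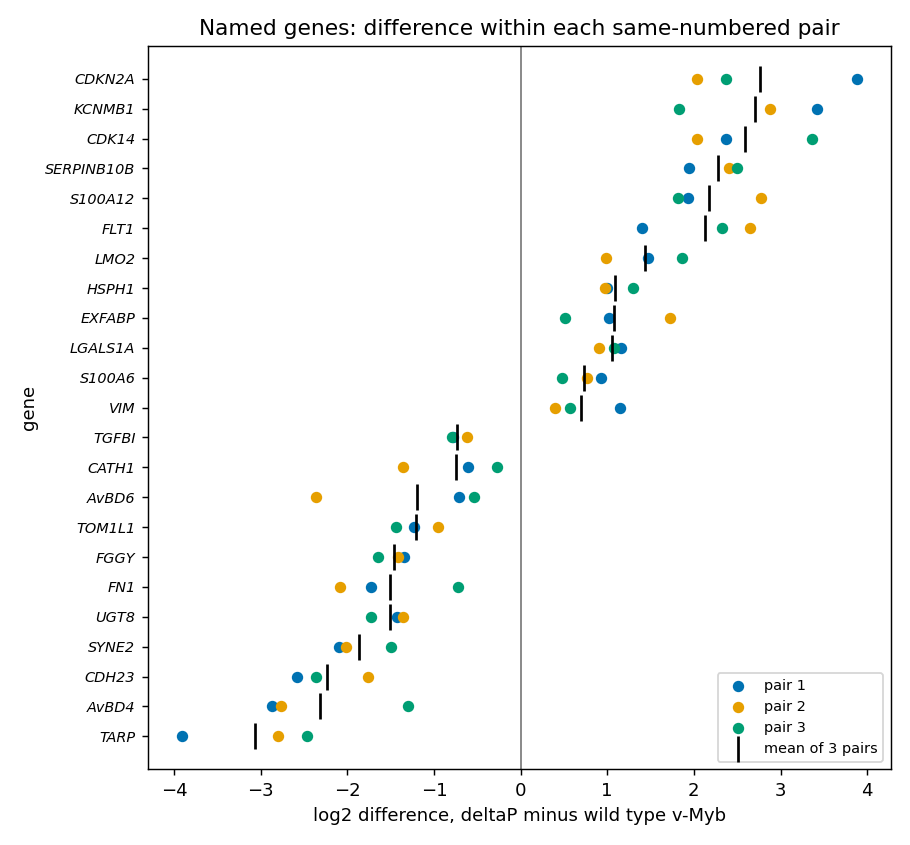
Log2 differences (deltaP minus wild type v-Myb) within each of the 3 same-numbered pairs, with a black bar at their mean, for the 10 genes with the smallest p and the 15 genes below the threshold when adjusted over their list alone. For the brightest probe set of every gene shown, all 3 pairs lay on one side of 0, from TARP at -3.06 to CDKN2A at 2.76.

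Within the 24 gene lists fixed in advance, 15 genes passed the threshold when adjusted over the list alone and 0 over all genes. Of these 15, 8 were higher and 7 lower in deltaP. Leaving out 1 array also removes the information in its partner, so the 6 such fits are not 6 separate checks. Whichever pair was affected, 9 of the 15 held: AvBD4, AvBD6, CDKN2A, EXFABP, FLT1, FN1, LMO2, S100A12 and TARP. CATH1 and HSPH1 held only without pair 3, S100A6, TOM1L1 and VIM were lost without pair 1, and TGFBI was lost without any 1 of the pairs. The lists are not independent of each other, since some genes stand in several.

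Genes of granulocytes and heterophils, the avian counterpart of neutrophils, differed in both directions. Of the antimicrobial peptide genes in the list, 3 passed the list-alone threshold: the avian beta-defensin AvBD4 fell 4.96-fold from a mean log2 value of 10.95, AvBD6 fell 2.3-fold and the cathelicidin CATH1 fell 1.68-fold. Their list-alone p in limma were 0.00293 for AvBD4, 0.0425 for AvBD6 and 0.0412 for CATH1. The defensin genes AvBD5, DEFB4A, AvBD1 and AvBD7 did not pass (list-alone p from 0.142 to 0.247), and each was lower in deltaP in pairs 1 and 2 and higher in pair 3. S100A12 rose 4.51-fold and EXFABP, a secreted lipocalin that binds siderophores, rose 2.12-fold, with list-alone p of 0.00191 and 0.0191. Of the 14 tested members 5 were higher and 9 lower, with a median of -0.38 and a camera adjusted p of 0.329. The list medians were -0.15, -1.06 and -0.03 in pairs 1, 2 and 3, so the lower values came mostly from pair 2. AvBD6 had differences of -0.71, -2.36 and -0.54 and CATH1 of -0.61, -1.36 and -0.27 in these pairs. Those of AvBD4 were -2.87, -2.76 and -1.3. The probe sets of AvBD4, AvBD5, AvBD6, AvBD7 and CATH1 are of the kind that can bind several related transcripts, so these values may include close family members.

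Monocyte and macrophage genes did not pass as a list, with 17 of 36 tested members higher and 19 lower (camera adjusted p = 0.789). TLR7, a receptor for single-stranded RNA, was 1.44-fold higher and the lysosomal protease gene CTSD 1.47-fold higher. LIPA, the lysosomal acid lipase, was 1.58-fold higher, while NCF1C, a subunit gene of the phagocyte NADPH oxidase, was 1.54-fold lower. All 4 had a list-alone p of 0.0995 in limma. In the lysosome list 22 of 39 members were higher (camera adjusted p = 0.541). MANBA, a lysosomal mannosidase, was 1.61-fold lower (list-alone adjusted p = 0.0864) and the protease gene CTSC was 1.28-fold higher (list-alone adjusted p = 0.123).

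Reported targets of Myb went both ways, 10 higher and 10 lower of 20 tested, with a median of -0.03 (camera adjusted p = 0.802). LMO2, a scaffold of hematopoietic transcription factor complexes, rose 2.71-fold in deltaP (log2 difference 1.44 ± 0.43, SD, n = 3 pairs). TOM1L1, a relative of the target-of-Myb adaptor TOM1, fell 2.31-fold (list-alone p of 0.00684 for both in limma). TOM1 itself was 1.4-fold lower and CEBPB, a myeloid transcription factor gene, 1.18-fold lower, with a list-alone p of 0.303 for both.

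LMO2 also passed the list-alone threshold in the hematopoietic progenitor list (adjusted p = 0.00845 in limma) and in the erythroid list (adjusted p = 0.00657 in limma). Among the other progenitor genes RUNX2 was 1.37-fold lower, NOTCH2 1.29-fold lower and RUNX1 1.31-fold lower, with list-alone p of 0.144, 0.144 and 0.251. Of 18 tested progenitor genes 9 were higher and 9 lower (camera adjusted p = 0.987), and of 14 erythroid genes 5 were higher and 9 lower (camera adjusted p = 0.735). TFRC, the transferrin receptor gene, was 1.69-fold higher with a list-alone p of 0.253.

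Lists named for other cell types included single genes past the list-alone threshold, and no such list passed as a whole with all arrays. The values do not show which cells expressed these genes, so they are no evidence of another cell type. The lymphocyte list was lower without the wild type array of pair 2 (median -0.34, camera adjusted p = 0.04), while with all arrays and an estimated correlation its adjusted p was 0.889. In the lymphocyte list TARP passed the list-alone threshold (adjusted p = 0.000492 in limma), BTK was 1.32-fold higher (list-alone adjusted p = 0.141) and 4 of 10 tested members were higher (camera adjusted p = 0.735). In the thrombocyte list F13A1, a coagulation factor subunit gene that macrophages also express, was 2.14-fold lower (list-alone adjusted p = 0.113), and 7 of 9 members were higher (camera adjusted p = 0.83). Of 40 fibroblast and stromal genes with a probe set, 8 were bright enough to test. FN1, which encodes fibronectin, fell 2.85-fold, S100A6 rose 1.66-fold and VIM, which encodes vimentin, rose 1.63-fold, with list-alone p of 0.00563, 0.00563 and 0.0146 in limma (camera adjusted p = 0.802). Of the endothelial and epithelial list 3 genes were tested, too few for a set test. FLT1, a receptor for vascular endothelial growth factor that monocytes also carry, rose 4.37-fold (list-alone adjusted p = 0.00113 in limma) and PECAM1 was 1.24-fold lower (list-alone adjusted p = 0.0724). A second, dimmer FLT1 probe set had a smaller mean log2 difference of 1.1, with 0.24, 1.61 and 1.46 in pairs 1, 2 and 3.

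Interferon response genes were the 1 list of 23 tested that passed the threshold in camera, with 29 of 35 members higher in deltaP, a median log2 difference of 0.42 and an adjusted p of 0.00115. The adjusted p was 0.889 with an estimated correlation and 0.769 in fry, so the call did not hold there. The shift came from pair 3, where the list median was 1.1 and 32 of 35 members were higher, against medians of 0 in pair 1 and 0.02 in pair 2. The GTPase gene MX1 had pair differences of 0.44, 0.35 and 3.3. The antiviral genes RSAD2 and OASL had pair 3 differences of 3.81 and 3, but pair 2 differences of -0.58 and -1.13. Without the wild type array of pair 3 the list median was -0.07 and the camera adjusted p 0.801. GBP, IRF7 and ADAR, which had the smallest p of the list, were 1.61-fold, 1.4-fold and 1.35-fold higher with a list-alone p of 0.232 each in limma. In the same pair the poly-A control RNAs added before labelling were higher on the deltaP array by a median of 0.68 and the hybridization controls by 0.5, against medians between -0.18 and 0.01 in the other pairs.

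**Figure D3:**
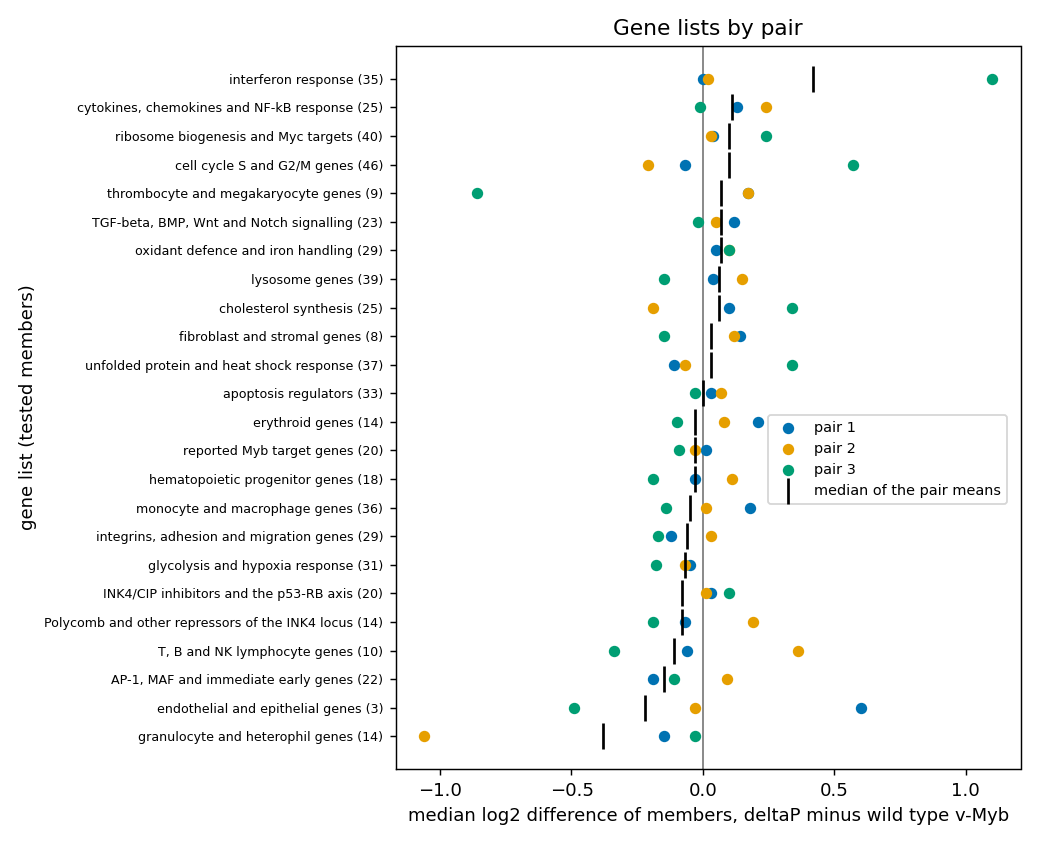
Median log2 difference (deltaP minus wild type v-Myb) of the tested members of each gene list within each of the 3 pairs, with a black bar at the median of the members' pair means. The interferon list stood at 1.1 in pair 3 and at 0 and 0.02 in pairs 1 and 2.

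Cell cycle genes of S phase and mitosis also followed pair 3. The list median was -0.07 in pair 1, -0.21 in pair 2 and 0.57 in pair 3, and 32 of 46 members were higher over the pairs (camera adjusted p = 0.12). Without the wild type array of pair 1 the list was higher in deltaP (camera adjusted p = 0.00104), as it was without that of pair 2 (camera adjusted p = 1.33e-05), and without that of pair 3 it was lower (camera adjusted p = 0.0355). These used the preset correlation, and with all arrays the estimated correlation of this list was 0.648 (adjusted p = 0.889 with that estimate). CCNE2, which encodes cyclin E2, was 1.4-fold higher and CCNA2, which encodes cyclin A2, 1.24-fold higher, each with a list-alone p of 0.84 in limma.

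Cytokine, chemokine and NF-kB response genes had 16 of 25 members higher (median 0.11, camera adjusted p = 0.22). SOCS1, an inhibitor of cytokine signalling, was 2.27-fold higher, the acute phase gene SAA 1.84-fold higher, the chemokine gene IL8L2 2.11-fold higher and the adaptor gene MYD88 1.4-fold higher. All 4 had a list-alone p of 0.0541 in limma, above the threshold of 0.05.

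Growth and biosynthesis lists did not pass the camera threshold with all arrays. In the ribosome biogenesis list 30 of 40 members were higher, with a median of 0.1 and a camera adjusted p of 0.0894. That list passed without the wild type array of pair 1 (camera adjusted p = 0.00915) or pair 2 (camera adjusted p = 0.0227), but not without that of pair 3 (camera adjusted p = 0.801). Its medians were 0.04, 0.03 and 0.24 in pairs 1, 2 and 3. WDR75 was 1.73-fold higher (list-alone adjusted p = 0.0573) and WDR12 1.47-fold lower (list-alone adjusted p = 0.202). Of 25 cholesterol synthesis genes 16 were higher (camera adjusted p = 0.334), with INSIG2 1.42-fold higher (list-alone adjusted p = 0.819). The cholesterol list passed without the wild type array of pair 2 (median 0.3, camera adjusted p = 0.000969). Its medians were 0.1, -0.19 and 0.34 in pairs 1, 2 and 3. Without the wild type array of pair 3 its median was -0.09 (camera adjusted p = 0.644). With all arrays and an estimated correlation, camera gave both lists an adjusted p of 0.889. Of 31 glycolysis and hypoxia genes 17 were lower (camera adjusted p = 0.232). There the lactate transporter gene SLC16A3 was 1.34-fold lower, the collagen prolyl hydroxylase gene P4HA1 1.72-fold lower and the glucose transporter gene SLC2A14 1.32-fold lower, each with a list-alone p of 0.18 in limma.

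Stress and survival lists gave 1 gene past the list-alone threshold. HSPH1, a chaperone of the heat shock response, rose 2.13-fold (list-alone adjusted p = 0.0354 in limma), and 23 of 37 members of its list were higher (camera adjusted p = 0.362). This list passed without the wild type array of pair 1 (camera adjusted p = 0.00514) or pair 2 (camera adjusted p = 0.0322). Its medians were -0.11, -0.07 and 0.34 in pairs 1, 2 and 3. Without the wild type array of pair 3 its median was -0.08 and it did not pass (camera adjusted p = 0.258). With all arrays and an estimated correlation its adjusted p was 0.889. In the oxidant defence and iron list 19 of 29 members were higher (camera adjusted p = 0.196). HEPH, a copper-containing iron oxidase, was 1.92-fold lower, while the glutathione transferase genes GSTA3 and MGST2 were 1.88-fold and 1.4-fold higher, each with a list-alone p of 0.0666 in limma. Of 33 apoptosis regulators 16 were higher (camera adjusted p = 0.677), and the death receptor adaptor gene FADD was 1.77-fold higher (list-alone adjusted p = 0.181).

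Adhesion and signalling lists did not pass the camera threshold either. CD82, a tetraspanin, was 1.72-fold lower (list-alone adjusted p = 0.0543) and ANXA1 2.66-fold higher with pair differences of 2.36, 0.15 and 1.72 (list-alone adjusted p = 0.177). The leukocyte integrin subunit gene ITGB2 was 1.26-fold lower (list-alone adjusted p = 0.177), and 19 of 29 members of this list were lower (camera adjusted p = 0.458). TGFBI, a secreted matrix protein gene, fell 1.66-fold (list-alone adjusted p = 0.0387 in limma) in the TGF-beta, BMP, Wnt and Notch list, where 13 of 23 members were higher (camera adjusted p = 0.789). SMAD1 was 1.5-fold lower there with a list-alone p of 0.203. Among AP-1, MAF and immediate early genes KLF6 was 1.41-fold higher and DUSP5 1.69-fold lower, each with a list-alone p of 0.356, and 12 of 22 members were lower (camera adjusted p = 0.789).

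Genes of the female-specific chromosome W differed within pairs, with opposite directions in pair 1 and the other two. In pair 1 their median log2 difference over 13 tested genes was 2.975, with 11 higher in deltaP, while it was -0.262 in pair 2 and -1.03 in pair 3. HINTW, a W-linked gene, had a log2 difference of 12.09 in pair 1. Its deposited values there were 5.8 on the wild type array and 17.89, the highest in the table, on the deltaP array. These follow from centring the pairs on a common mean and are not measured levels. A second, dimmer HINTW probe set had differences of 2.62, -1.26 and -1.89 in pairs 1, 2 and 3. The 380 tested genes of chromosome Z, which carries CDKN2A, had medians of -0.099, 0.118 and 0.155 in pairs 1, 2 and 3. The corresponding medians over 7301 genes of the other chromosomes were 0.035, 0.016 and -0.052.

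**Figure D4:**
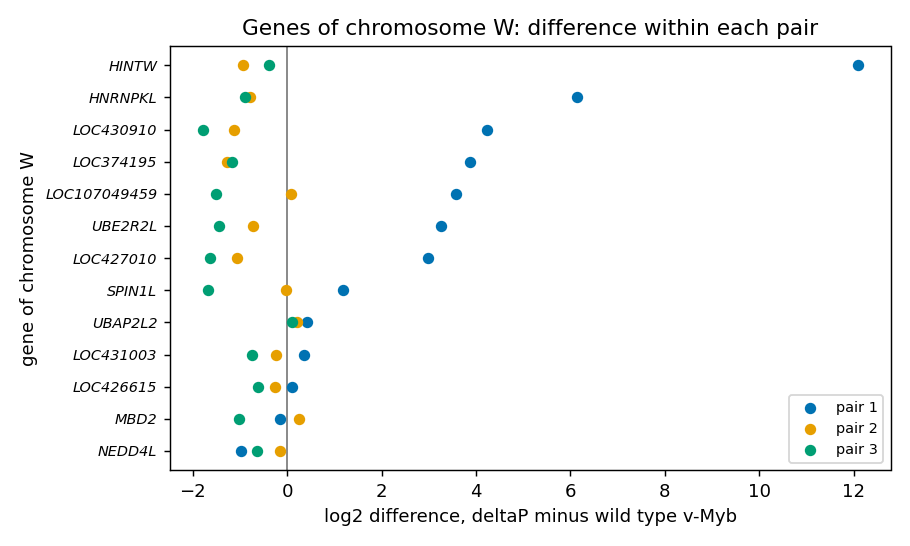
Log2 differences (deltaP minus wild type v-Myb) of the 13 tested genes of chromosome W within each of the 3 pairs. HINTW, shown by its brightest probe set, reached 12.09 in pair 1, against -0.94 in pair 2 and -0.38 in pair 3.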

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

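The pair weights, the removal of Z and W genes and the use of the fit with the replicate block in place of the fit fixed first were chosen after seeing the data. The log2 difference of CDKN2A kept its direction in every setting, and lay between 2.2 and 3.12 with 1 array left out. Without the replicate block limma called 1120 probe sets, 640 genes and 76 genes over their list alone, and the CDKN2A difference of 2.76 passed the threshold. The fit counts 4 residual degrees of freedom where 2 exist, and called 200.2 probe sets on average on simulated values with no change. With the added threshold of 2-fold, 170 probe sets and 94 genes passed without the block. The block changed no call of a gene list. Without the filter 3 lists passed and 7 genes passed over their list alone, and with the filter at 6 the latter were 23. With an estimated correlation 0 lists passed and in fry 0 lists passed. With pair weights (2, 1.12 and 0.45 for pairs 1, 2 and 3) 29 genes passed, 15 higher and 14 lower, and 37 passed over their list alone. CDKN2A was among the 29, with a log2 difference of 3.11 and an adjusted p of 0.0464. Leaving out 1 array gave 0 to 12 probe sets past the threshold (11 and 12 without the wild type or the deltaP array of pair 3), 1 to 6 gene lists (4 without pair 1, 6 without pair 2), and 11 to 23 genes over their list alone (23 without pair 3). Genes past the threshold over all genes stayed at 0 with any 1 array left out. The causes of these changes were not tested.

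Some values changed sign. Apart from the interferon list, which had passed in camera with the preset correlation, none of these was past a threshold. With pair weights CDH1 was at 0.05 and FLI1 at 0. With 1 array left out, LECT2 ranged from -0.56 (without pair 1) to 1.28, SELP from -0.1 (without pair 1) to 1.37, CDH1 from -0.62 to 0.01 (without pair 2), PDGFA from -0.16 (without pair 3) to 1.46, and the median of the interferon list from -0.07 (without pair 3) to 0.71. The cause was not tested. Of 1575 alternative values for the 98 genes named or compared and the interferon list, 1485 kept their direction and side of the threshold. A further 76 came past it in the same direction (62 without the block and 14 with pair weights), 2 were weaker and 12 changed sign. No gene was past the threshold over all genes in the main fit, so keeping its side asked little. Leaving out either array of a pair was also counted separately. These counts are therefore no measure of robustness. Signal over background limits the dim genes: of the genes named, CDKN2B, MYB, CDK14, CDH23, RSAD2 and PDGFA had a group mean below the filter value.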

Other observations

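The tests on CDKN2A and on the W-linked genes were chosen after the results were seen, and so were the genes of this paragraph and the next. AHR1A, which encodes an aryl hydrocarbon receptor, was 9.17-fold higher in deltaP (log2 differences of 4.46, 3.72 and 1.41, adjusted p = 0.213 in limma). CYP1A1, a classic target of that receptor, was higher in pair 1 alone, with differences of 2.19, -0.04 and 0.08. NT5E, the ecto-enzyme that makes adenosine, was 2.47-fold higher, the nucleotide receptor gene P2RY6 1.71-fold higher and the monoamine oxidase gene MAOA 3.09-fold higher, while TPH2, a tryptophan hydroxylase, was 3.45-fold lower. The retinoid-responsive gene RARRES1 was 2.88-fold higher and the surface antigen gene CD99 2.01-fold higher. The adjusted p of these 6 genes in limma ran from 0.166 to 0.189, so none passed the threshold.

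Among genes lower in deltaP, the circadian repressor PER3 was 2.88-fold lower and its relative PER2 1.46-fold lower, with adjusted p of 0.182 and 0.477 in limma. SOCS2, an inhibitor of cytokine signalling, was 2.31-fold lower, against the higher values of SOCS1. The Wnt antagonist gene FRZB was 3.54-fold lower, the tetraspanin gene TSPAN8 2.75-fold lower, the lipid carrier gene PCTP 2.29-fold lower, the transcriptional cofactor gene CITED4 1.95-fold lower and the necroptosis kinase gene RIPK3 1.46-fold lower. From SOCS2 to RIPK3 the adjusted p in limma ran from 0.182 to 0.25. The largest mean difference on the array belonged to a probe set without a gene symbol, which was 63.4-fold higher in deltaP with differences of 8.03, 7.44 and 2.49 (adjusted p = 0.28 in limma). Another probe set without a symbol was 8.4-fold higher, with uneven differences of 1.16, 5.18 and 2.87 (adjusted p = 0.351 in limma). Of 2 more, 1 was 10.3-fold lower (-3.99, -3.16 and -2.96, adjusted p = 0.13 in limma), which shares the cluster number of the TARP probe sets and is not counted as a separate observation, and 1 was 8.42-fold lower (-3.72, -2.17 and -3.33, adjusted p = 0.191 in limma).

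CDKN2A was higher in the deltaP array of every pair. It lies on chromosome Z, so a different sex composition of the cells within a pair could move it. That would lower it where W-linked genes were higher, yet it was higher by 3.88 in pair 1. In pairs 2 and 3 the W-linked medians were -0.262 and -1.03, so a sex difference there would raise CDKN2A. Those 2 pairs therefore cannot speak against this explanation. A change of the whole neighbourhood would raise the adjacent genes, and the median of the 8 tested neighbours was -0.04, the largest size being 0.81 for ZNF608, which was lower. The filter left CDKN2B out of these 8, and it had differences of 2.96, 0.03 and 0.05, so a change shared by CDKN2A and CDKN2B in pair 1 stays open. The shift of the spiked controls in pair 3 would leave the other pairs without a difference, but the smallest difference there was 2.04. A dependence on the form of v-Myb stays open as a hypothesis, as do clonal differences between the transformed cultures, and neither was tested by itself.

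The interferon response list was higher in deltaP through pair 3. The shift seen in the spiked controls of that pair, if shared by other probe sets, would move random lists of like expression as far. The interferon list lay at percentile 100 of 10000 matched random lists there, against 30.7 in pair 1 and 55.42 in pair 2. A state of the cultures of pair 3 alone is a candidate explanation for the list median. Camera gave an adjusted p of 0.801 without the wild type array of pair 3, and 7.75e-09 and 5.62e-07 without that of pair 1 or 2. These camera fits used the preset correlation of 0.01. They follow from the list medians of 0, 0.02 and 1.1 in pairs 1, 2 and 3 and are no separate support. Single members also differed in pair 2: IFI6, IFIT5, OASL and IFI27L2 had differences of -1.95, -1.52, -1.13 and -1.08. Of all 35 members, 18 were higher there. GBP, IRF7 and ADAR were higher in every pair. With all arrays and the estimated correlation of 0.44, the list did not pass (adjusted p = 0.889). Whether the deltaP culture was stimulated or the wild type culture was low cannot be read from values centred within the pair.

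W-linked genes differed within pairs. A different sex composition of the cells within a pair is a candidate explanation: Z-linked genes shifted against W-linked genes, relative to the other chromosomes, in 3 of 3 pairs. That compares directions only, and the sizes did not follow each other. The W-linked median was 2.975 in pair 1 and -1.03 in pair 3, while the Z-linked median was -0.099 in pair 1 and 0.155 in pair 3. No explanation from the study's groups was tested for this pattern.

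Other splits of the 6 arrays bear on the counts. Without the block, the real split gave 1120 probe sets and the highest of the other 9 splits 61, so 1 of 10 splits gave as many. Only 4 of these splits keep the pairs, and the 6 that break them all gave 0, so among comparable splits it was 1 of 4. With the block, only those 4 splits were run. The real one gave 1500 probe sets at an unadjusted p under 0.05 against 754 in the highest other, so 1 of 4 gave as many. For genes it gave 771 against 396, again 1 of 4. For gene lists past the threshold it gave 1 against 6 in the highest other, so 4 of 4 gave as many. Neither 10 nor 4 splits can give a share under 0.05. The splits that turn pair 1, 2 or 3 gave 4, 6 and 4 lists, several times the real count. Whether a structure of the pairs or the correlation within lists (0.648 estimated for the cell cycle list, against the preset 0.01) gave these counts was not tested.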
